A study of Mus musculus with 3 samples.

How the data were processed

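The study profiled T cells from mice treated with the skin bacterium Staphylococcus epidermidis, a common commensal. Per the labels, cells came from skin, spleen and LN (written here as the labels write it) of wild-type mice, and single-cell libraries were made with a 10x Genomics 5′ kit. In such a kit each droplet carries a bead whose oligonucleotides share one cell barcode. The labels list 3 libraries made from 1 pool of cells: a gene expression library, a hashtag library and a V(D)J library. A hashtag is an antibody joined to a short DNA tag, and cells from each mouse and tissue are stained with their own tag before pooling. A V(D)J library reads the rearranged antigen receptor chains. Per the labels' protocol for skin, ear tissue was digested and mechanically dissociated before red cells were lysed.

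The deposited files used here are 3 lists of text with no measured value in them: the hashtag table, the cell barcode list of the filtered matrix, and its feature list. Per the submitters' processing notes, Cell Ranger and Seurat were used with the mouse build mm10, and their versions and settings are not given in the sources used here. The counts behind the matrix, the link from each barcode to a hashtag, the cell annotation and the receptor sequences were not analysed here. The number of reads or molecules per library and per cell is therefore unknown here. Doublets, droplets that hold more than 1 cell, were not called or removed here, since that needs counts, and whether the 27775 listed barcodes include them is not known here. No expression level, cell type share or difference between tissues or mice could be computed, and no gene was tested.

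The following was computed from the lists, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Hashtag names were split into mouse number, the letter F or M, and tissue. The letters are reported as written, since the labels do not define them. Tag sequences were compared by Hamming distance, the number of positions that differ. Each barcode was split into its 16 bases and its suffix, which in aggregated matrices of this kind marks the well a cell was captured in. Sequences found under more than 1 suffix were counted. The size of the barcode pool was estimated by capture-recapture, as the sum over pairs of suffixes of the product of their list lengths divided by the sum of their overlaps. Intervals are exact Poisson intervals at 95% for counts and exact Clopper-Pearson intervals at 95% for shares, and they cover counting error only. The barcode steps were tested on simulated data. For 27775 simulated barcodes, the estimated pool was 105% of the true size, and all 160 planted pairs of neighbouring sequences were recovered. The simulated sequences were random, drawn from a smaller pool than that estimated here, and lacked the structure of the listed barcodes. The simulation therefore checks the computation only, not how well the method suits the listed barcodes.

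Gene features were matched by Ensembl identifier to a table of gene names, which held 27645 of the 27998 identifiers, or 98.7%. Coordinates and gene classes (protein coding, snoRNA and so on) came from a RefSeq annotation of GRCm38.p6, the assembly that mm10 names, joined by gene symbol. A class member counted as listed when the identifier given to its symbol was among the gene features. The 24 lists of cell type markers, the choice of named genes (list members, given by name where a list is incomplete, and the hashtags) and the alternatives were fixed before the data were examined. Genes of complete lists that are named below are examples chosen afterwards. Some list members are not reported here by name. The alternatives were other ways to count barcodes, features, receptor segments, list members and tag distances. Planned tests of expression between hashtag groups were not run, because they need counts.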

Results

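T cells from skin, LN and spleen of mice treated with Staphylococcus epidermidis were pooled and read as 3 single-cell libraries, for gene expression, hashtags and antigen receptors. The gene expression matrix listed 27775 cell barcodes and 28020 features, of which 27998 were genes and 22 were hashtags. Each library type had 1 sample, so no comparison between samples of a group was possible. Expression values were not analysed here, and nothing in the lists says how strongly any gene was expressed in any tissue.

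The hashtags set out a comparison of tissues within mice. The tags in the table used here are numbered 1 to 16 and 19 to 24, and tags 17 and 18 were not analysed here, so the counts of mice and tissues below are of these 22 tags. Their names covered 10 mice, 4 with the letter F and 6 with the letter M. All 10 mice had a skin tag. Mice 1 to 6 also had an LN tag and a spleen tag, and they comprised the 4 F mice and 2 M mice. The other 4 mice, all M, had only a skin tag among these 22. T cells of skin can thus be set against those of LN and spleen within 6 mice, while the F and M mice can be compared 4 against 6 in skin and 4 against 2 in the other tissues.

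**Figure D1:**
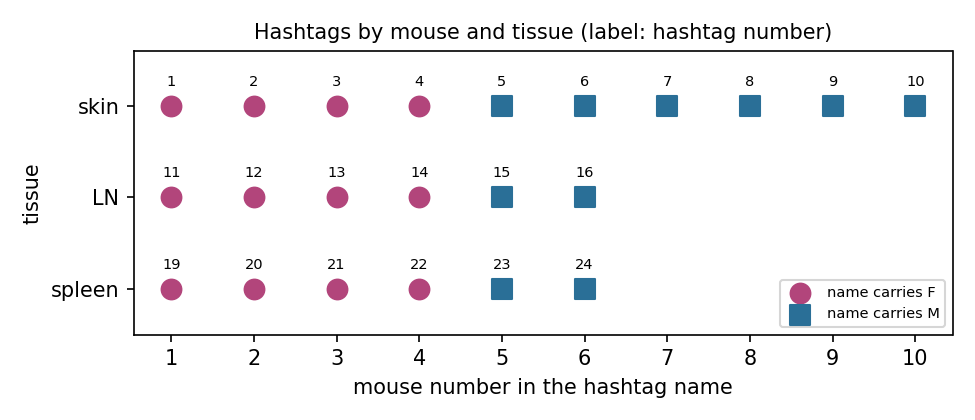
Tags by mouse number (horizontal axis) and tissue (vertical axis), with circles for names that carry F, squares for names that carry M, and the hashtag number above each point. All 10 mice have a skin tag, and mice 1 to 6 also have LN and spleen tags.

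With the mouse as the replicate, the layout of these 22 tags fixes the smallest p-value an exact two-sided permutation test of 1 value could give. A tissue difference within the 6 mice could reach 0.0312. For F against M in skin, with 4 and 6 mice, the floor of an exact permutation test is 0.00952 when the smaller one-sided p is doubled and 0.00476 when absolute differences are ranked. In LN or spleen, with 4 and 2 mice, the floors of an exact permutation test are 0.133 and 0.0667, so neither form could pass a threshold of 0.05. If cells were spread evenly, each tag would hold an average of 1262.5 barcodes, but the barcodes assigned to each tag were not analysed here.

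The tags themselves were well separated. Each was 15 bases long, and the 231 pairs of tags differed at a median of 11 positions. The smallest difference was 6 positions, seen in 2 pairs. One was the LN tag CTACATTGCGATTTG and the spleen tag CTTTAGTTCGTTGTG, both of mouse 3. The other was the LN tag of mouse 6, GATGTATCCGTTGTC, and the spleen tag of mouse 2, CAAGTATCTGCCGTG. A read with up to 2 base substitutions in its tag therefore stays closest to the tag it came from.

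Genes that define the main helper and effector T cell states were countable. Every member was a feature in 21 of the 24 marker lists, and 83 of the 94 marker symbols were listed. Of 20970 protein-coding genes, 97.1% were listed, so complete marker lists lie near the share over all such genes. They show what could be counted and say nothing about the cells. All 8 genes of the follicular helper list were present. Among them were Cxcr5 (ENSMUSG00000047880), the chemokine receptor that guides cells to B cell follicles, at chromosome 9 from 44511787 to 44526444 of GRCm38.p6, and Bcl6 (ENSMUSG00000022508), the transcription factor that directs the follicular helper programme, at chromosome 16 from 23965050 to 23988866. Il21 (ENSMUSG00000027718), a cytokine that acts on B cells, lies at chromosome 3 from 37222759 to 37232636. These spans are whole genes. All 4 regulatory T cell genes were listed, including Foxp3 (ENSMUSG00000039521), as were all 5 type 17 genes, including Il17a (ENSMUSG00000025929). The type 1 list (3 genes, with Ifng), the type 2 list (4 genes, with Il4), the naive list (5 genes, with Ccr7) and the resident memory list (4 genes, with Itgae and Cxcr6) were complete. The CD4 and CD8 lists, with 3 genes each, were complete too.

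Antigen receptor genes were the exception. None of the 6 symbols of the gamma-delta T cell list was a feature (Trdc, Trgc1, Trgc2, Trdv4, Tcrg-C1 and Tcrg-C2, which include alternative symbols for the receptor's constant regions). In the T cell list, Cd3e, Cd3d and Cd3g, the invariant chains of the receptor complex, were listed, while Trac, Trbc1 and Trbc2, the constant regions of the alpha and beta chains, were not. In the B cell list, Ms4a1, Cd79a and Cd79b were listed, while Ighm and Ighd, the heavy chain constant regions of IgM and IgD, were not. Of 8 heavy chain constant genes looked up, including Igha and Ighg1, 0 were features. A search for V, D, J and C segments of the 3 immunoglobulin and 4 T cell receptor loci found 0.

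Apart from the B cell list, with 4 of 6 genes, the marker lists of other cells that a T cell preparation from these tissues could hold were complete. The plasma cell list had 5 of 5 genes, with Jchain and Sdc1, and the list for natural killer cells had 3 of 3. The lists for macrophages or monocytes and for dendritic cells had 4 of 4 each, and those for neutrophils and mast cells had 3 of 3 each. The Langerhans cell list, with Cd207 and Epcam, had 2 of 2. The keratinocyte, fibroblast and cycling lists had 3 of 3 each, and the endothelial and red cell lists had 2 of 2 each. With 97.1% of protein-coding genes listed, complete lists say nothing about whether such cells were present.

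The cell barcodes carried 4 suffixes. Suffix 1 had 7416 barcodes (95% exact Poisson interval 7248 to 7587), suffix 2 had 7184 (7019 to 7352), suffix 3 had 6491 (6334 to 6651) and suffix 4 had 6684 (6525 to 6846). The intervals of suffixes 1 and 2 lay above those of suffixes 3 and 4, so the lists differed by more than counting error. If the suffixes mark wells loaded alike from the 1 pool of cells, these 4 counts are themselves the spread between wells. Whether the wells were loaded alike is not known here. The barcodes came from 27396 distinct sequences, of which 374, or 1.37%, occurred under more than 1 suffix, so a barcode identifies a cell only together with its suffix. Of these, 369 occurred under exactly 2 suffixes and 5 under exactly 3. Summed over the 6 pairs of suffixes there were 384 shared sequences. They gave an estimated pool of 752649 barcodes (95% interval 681010 to 833988, which assumes even draws). Estimates from single pairs ran from 563453 for suffixes 3 and 4 to 991371 for suffixes 1 and 4. Both lay outside that interval, but each rests on fewer overlaps and has a wider counting error of its own. For suffixes 3 and 4 the interval of the 77 shared sequences (60.8 to 96.2) excluded the 57.6 expected from the pooled estimate. For suffixes 1 and 4 the interval of the 50 shared sequences (37.11 to 65.92) just included the 65.86 expected.

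**Figure D2:**
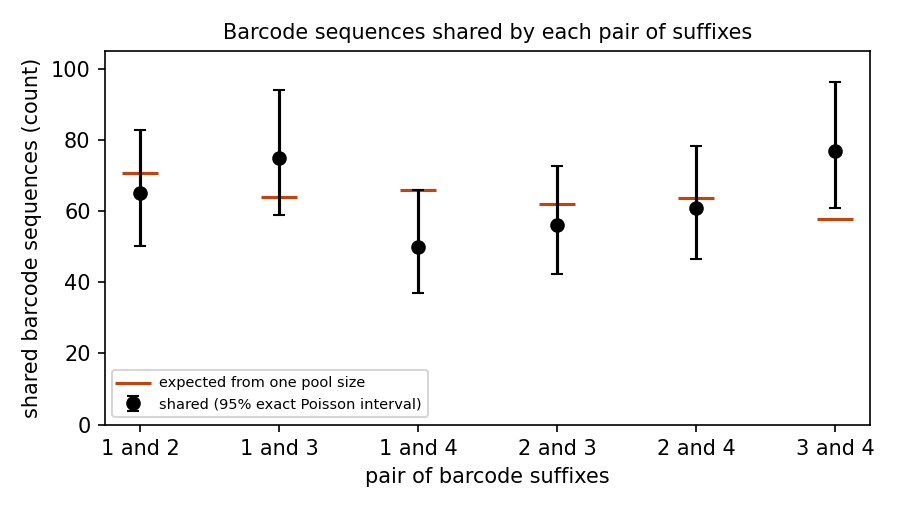
Number of barcode sequences shared by each pair of suffixes (points, with 95% exact Poisson intervals) and the number expected if all suffixes drew evenly from one pool (horizontal marks). Suffixes 3 and 4 shared 77 sequences where 57.6 were expected, and suffixes 1 and 4 shared 50 where 65.9 were expected.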

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

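Every alternative reported here was planned before the data were examined. The smallest distance between hashtags fell from 6 to 5 when insertions and deletions were allowed (edit distance). The pair at 5 was another one, the skin tag of mouse 5 and the spleen tag of mouse 3, which differ at 7 positions, while both pairs at 6 positions also had an edit distance of 6. The 5 counts of barcodes, features and genes stayed within 1.5 times their main value. Distinct sequences numbered 27396 against 27775 barcodes. Overlaps summed over pairs of suffixes came to 384 with or without 1 mismatch. Distinct symbols numbered 27933 against 27998 gene identifiers. There were 0 receptor segments when only V segments were searched, and 83 marker symbols with letter case ignored. The mismatch setting moved nothing, since no pair of listed sequences was 1 base apart. The search for V segments could give only 0 once all segments together gave 0. Ignoring letter case could raise 83 to at most 94, the number of marker symbols, which is within 1.5 times. None of these settings says anything about stability. Other settings for expression levels and for tests between hashtag groups were also fixed in advance and were not run, because they need counts that were not analysed here. No paired analysis was possible because no value per mouse or tissue was analysed here. Read depth is unknown here, so no limit on detection can be given.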

Other observations

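The tests of whole gene classes by identifier, and of the number of sequences under 3 or more suffixes and of neighbouring barcodes, were written down before their results were seen. The tests on barcode parts and on unequal overlaps were chosen after the barcode list had been examined.

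Antigen receptor genes were missing as a class from the features in the list used here. A different naming of the same genes does not account for this. Of 663 immunoglobulin and T cell receptor gene identifiers in the gene name table, 0% were gene features (95% upper bound 0.555%). All receptor identifiers in the gene name table were looked up, so this is a full count and the bound measures no sampling error. A candidate explanation is a gene list limited to some classes of gene. Of 3183 snoRNA, miRNA and snRNA genes, 0.0314% were listed, against 97.1% of 20970 protein-coding genes and 59.1% of 4750 long noncoding RNA genes. Whether the list was limited when the alignment reference was built or at a later step stays open. With the features in this list alone, immunoglobulin isotypes and gamma-delta receptor chains could not be counted by gene symbol. The list used here may lack rows of the original, and which chains the V(D)J library covers was not analysed here.

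The suffixes may mark wells that drew their barcodes from one pool. The test written in advance went with even draws. Sequences under 3 or more suffixes numbered 5 (95% exact Poisson interval 1.62 to 11.7), and even draws from the estimated pool would give 2.34. The test could detect only a large excess, since so few were expected and the pool size was fitted to the same overlaps. Its result is therefore weak support. The distinct first 7 bases (480) and last 8 bases (1535) multiply to 736800, inside the 95% interval of the pool estimated from overlaps. That interval assumes even draws. The range of 563453 to 991371 from single pairs contains the interval, so it is no separate check. The product fits a pool in which every first part joins every last part. The tests chosen after the overlaps were seen went against even draws. Of 10000 simulated draws, a share of 0.0178 had an excess in any one pair as large as that of suffixes 3 and 4, and a share of 0.0163 had overlaps as unequal across all 6 pairs. An uneven draw is therefore only a hypothesis, found and tested on the same list. Transfer of barcodes between wells was not tested, and no biological explanation was tested.

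Sequencing errors that turn one barcode into a neighbour in the same well would leave an excess of pairs 1 base apart within suffixes, but the list cannot answer whether they occurred. There were 0 such pairs within suffixes and none across them, where random sequences would give 4.19 pairs in all. By contrast 7096 pairs were exactly 2 bases apart, where random sequences would give 94.4. Only 4 of 16 possible base pairs occurred at positions 8 and 9, counted from the first base. With no neighbours across suffixes to compare against, the ratio that the test needed is undefined. If the listed sequences come from a set without neighbours, 0 pairs within suffixes was fixed in advance and says nothing about errors.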
